A study of Rattus norvegicus with 15 samples.

How the data were processed

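The data are circRNA profiles of whole blood from male Sprague-Dawley rats. Per the labels' protocols, blood was collected and RNA extracted with the PAXgene blood system, libraries were made from total RNA with the NEBNext Ultra kit, and sequencing was paired-end. The 15 libraries fall into 5 groups of 3 by the time after modelling given in the labels. The messenger RNA profiles that the series design mentions were not used here.

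The deposited file is 1 table of 43472 circRNAs by 15 libraries. Per the file's name, the circRNAs come from find_circ, a tool that finds reads spanning a back-splice, and the signal is SRPBM, back-spliced reads per 1e9 mapped reads, as normalized by the authors. The submitters' processing notes list Bowtie 0.12.2 and the rat genome build Rnor_6.0, without their role; thresholds on circRNA calls are not given in the sources used here. In each library every value above 0 was a whole multiple of a single step (100% of values, within 0.01 read), with 2 as the smallest multiple, so the step gave the mapped reads of each library (66.0 to 92.4 M, with M for 1e6) and the back-spliced reads behind each value. The table lists only values from 2 reads up, so a count limit for a value of 0 was not used, and a 0 is given as listed at 0. PCR copies are not independent molecules, so intervals cover counting error only. No 2 libraries held identical values (0 identical pairs).

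The table names circRNAs by running numbers and pairs none with a host gene, a coordinate or an outside identifier. Summing per host gene, 6 host gene comparisons, 13 host gene lists for blood cell types and pathways, and the circRNA in the series title had been planned before the data were examined. None could be computed, and they are not analysed here.

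Differences between groups were tested per circRNA with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of the spread on mean abundance) on log2(SRPBM + 23.2), where the pseudocount is the median over the 15 libraries of the smallest value above 0. A log2 change on this scale understates the change of low circRNAs, and where libraries are listed at 0 it depends on the pseudocount. For a group with all libraries at 0 no fold is given. CircRNAs above 0 in at least 3 of the 15 libraries were tested (16767), all 5 groups entered 1 fit so that they share an estimate of the spread, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each of the 4 times against sham, 3 d against 1 h, 12 h against 6 h, and library set C against A&B. The mean of the 4 times against sham was added after the data were seen. CircRNAs detected and total signal per library were compared with two-sided exact permutation tests, 12 in the family.

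CircRNAs were named by a rule fixed before the data were examined: in each comparison, those with the largest change in each direction among circRNAs past the threshold whose groups do not overlap, then those with the smallest p, and the 10 with the highest mean over all libraries. Since the identifiers carry no gene, at most 2 per direction are named in a comparison, except where the text says a circRNA was chosen after its values were seen.

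The fit was tested on simulated data. For 1 h against sham, 16767 circRNAs were simulated from the observed means of values above 0. Zeros were drawn separately in each library at each circRNA's observed share. Draws under 2 reads were also set to 0, so low circRNAs could hold more zeros than observed. Of these circRNAs, 100 were changed by 4-fold and 100 by 16-fold (all above 0 in at least 12 libraries). Limma called 4% of the 4-fold and 41% of the 16-fold changes, and 33.8% of its calls were circRNAs that had not been changed. The median fitted log2 changes of the 4-fold and 16-fold sets were 1.85 and 3.80. In 20 simulated tables with nothing changed it still made calls, whose numbers stand beside the observed ones. The test is therefore more permissive than its threshold states on data simulated in this way, and it has little power for 4-fold changes.

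The 2 libraries with fewest circRNAs (sham replicate 2 with 2958 and 1 h replicate 1 with 2551) had 66.0 and 73.3 M mapped reads. Their median listed circRNA had 16 and 10 reads, against 6 or 7 in the other 13, and 2.54% (95% Wilson interval 2.03 to 3.17) and 9.88% (8.78 to 11.1) of their circRNAs had 2 or 3 reads, against 19.3% to 29.0%. Spearman correlations across circRNAs between a library of this pair and another had a median of 0.37 (27 pairs), against 0.57 for other pairs within a group (11 pairs) and 0.56 for other pairs between groups (67 pairs); circRNAs are not independent replicates.

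Alternatives planned before the data were examined were other pseudocounts (1 SRPBM, and 10 times the main one), no filter, a filter of at least 8 libraries, scaling to the total circRNA signal or by median ratios, limma without the trend, a replicate block, a fit of only the 2 groups compared, and leaving out each replicate in turn. Alternatives added after seeing the data were leaving out the 2 libraries with fewest circRNAs, array weights, limma voom on the back-spliced reads, zeros as missing values, and, for all DVT times against sham, a fit within library set A&B only. An alternative in which a named circRNA was not tested, such as the stricter filter, is not counted for it. The number of alternatives therefore differs, and a circRNA listed in few libraries is not charged with settings that exclude it. Scripts were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.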

Results

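Circular RNAs (circRNAs), closed loops made when a downstream splice donor joins an upstream acceptor, were measured in whole blood of male Sprague-Dawley rats, an outbred laboratory strain, after modelling of deep venous thrombosis (DVT), the formation of a clot in a deep vein. Blood was taken from a sham group (0 h) and at 1 h, 6 h, 12 h and 3 d (72 h) after modelling, with 3 libraries in each of the 5 groups. The labels do not say that the 3 libraries of a group came from separate animals, so the spread between these libraries may be technical. The limma p-values and SEs rest on a spread estimated largely from circRNAs of like mean abundance. They can therefore understate the spread between the libraries of a single circRNA. The sample titles carry 2 prefixes, 1 ending in A&B (sham, 1 h and 3 d, 9 libraries) and 1 in C (6 h and 12 h, 6 libraries). They are read here as library sets A&B and C. The titles do not say what the prefixes stand for. Values are SRPBM, back-spliced reads of a circRNA per 1e9 mapped reads of its library, and M stands for 1e6. The mapped reads behind them, recovered from the steps between values, ran from 66.0 to 92.4 M per library.

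The table listed 43472 circRNAs, of which 20878 (48.0%) were above 0 in a single library and 886 in all 15. The file names each circRNA by a running number and pairs it with neither a host gene nor coordinates, so circRNAs are given here by that number, and the circRNA in the title of the series could not be matched to a row. Levels rested on few reads for most circRNAs. In the 13 libraries other than sham replicate 2 and 1 h replicate 1, the median listed circRNA had 6 or 7 reads, and no value above 0 stood for fewer than 2. Among circRNAs above 0 in at least 7 of those 13 libraries, a limit that caps the share of zeros and leaves out most circRNAs, those with a median of 4 to 8 reads were listed at 0 in 29.9% of values, against 0.70% for those with 64 to 128 reads. In sham replicate 2 and 1 h replicate 1, which stayed in the main fit, the same 2 classes were listed at 0 in 92.3% and 22.3% of values. A value of 0 is therefore given as listed at 0, library by library, and not as absence.

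CircRNAs were counted in each library to ask whether the circRNA repertoire of blood grew or shrank with time. The sham libraries held 8324 ± 4861 circRNAs (SD, n = 3), the 1 h libraries 9855 ± 6593, the 6 h libraries 12611 ± 2189, the 12 h libraries 12630.3 ± 1834 and the 3 d libraries 10187 ± 722 (each n = 3). The wide spread at sham and 1 h came from 1 library in each: sham replicate 2 held 2958 circRNAs against 9583 and 12432 in the other sham libraries, and 1 h replicate 1 held 2551 against 11647 and 15366. None of the 6 comparisons between groups passed a two-sided exact permutation test (p from 0.2 to 1, adjusted p 0.96 or above over 12 tests), and 3 libraries against 3 cannot give a p under 0.1. The largest difference, 12 h over sham, was 1.52-fold, and was smaller than the SD of the sham libraries.

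**Figure D1:**
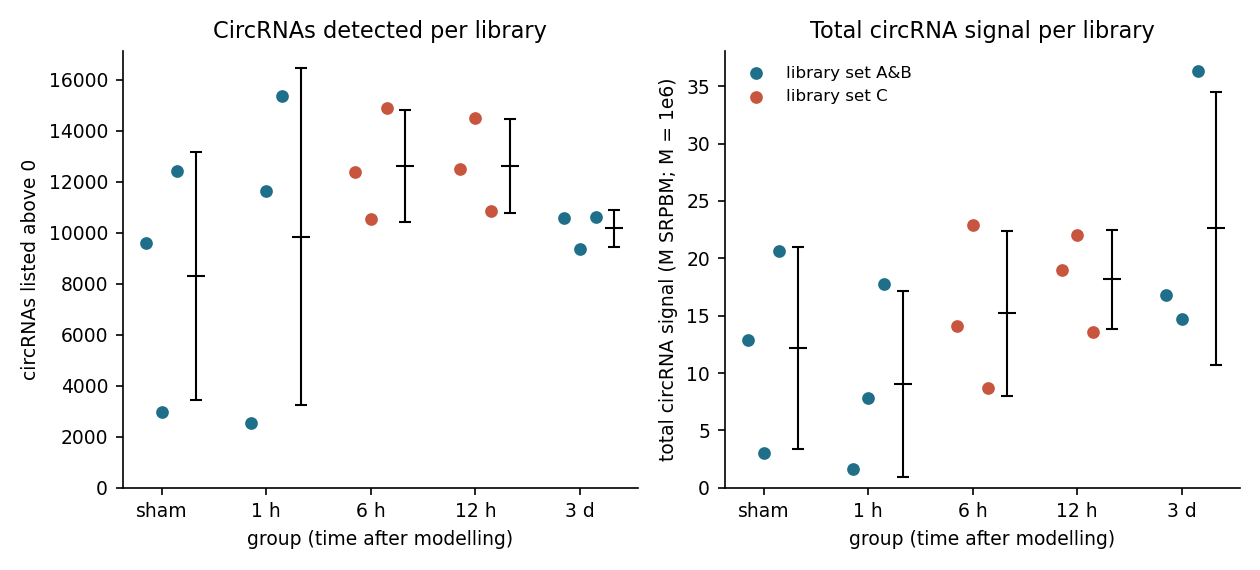
CircRNAs listed above 0 (left) and total circRNA signal in M SRPBM (right) for each of the 15 libraries, by group and coloured by library set; the black mark and bar are the group mean and SD (n = 3). Sham replicate 2 and 1 h replicate 1 lie at 2958 and 2551 circRNAs, below the other 13 libraries, which hold 9354 to 15366.

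The total circRNA signal averaged 12.2 ± 8.83 M SRPBM at sham, 9.05 ± 8.12 M at 1 h, 15.2 ± 7.16 M at 6 h, 18.2 ± 4.31 M at 12 h and 22.6 ± 11.9 M at 3 d (SD, n = 3 each). The 3 d mean was 2.50-fold that of 1 h, with exact permutation p = 0.3 and adjusted p = 0.96. That ratio rested on the most abundant circRNAs: without the 10 highest, the totals were 2.39 ± 0.17 M at 3 d and 2.49 ± 1.46 M at 1 h (n = 3 each).

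The 4 circRNAs with the highest means took 81.8% of all circRNA signal. CBT15_circR_5191 averaged 9.61 M SRPBM, lay between 8.74 and 28.7 M in 11 libraries and was listed at 0 in the other 4 (sham replicate 2, 1 h replicates 1 and 2, and 6 h replicate 3). In the 11 libraries it took from 55.6% (95% Wilson interval 55.5 to 55.7) to 79.0% (78.9 to 79.0) of the back-spliced reads, intervals that cover counting error only. CBT15_circR_5185 was present in all 15 libraries at 0.656 to 4.90 M. CBT15_circR_5184 was listed in 5 libraries, at 1.12 to 2.11 M (all 3 at 12 h, 1 h replicate 2 and 6 h replicate 3). CBT15_circR_1124 was listed in 3, at 1.34 to 2.21 M (1 h replicate 3, 6 h replicate 2 and 12 h replicate 2). Below these 4, CBT15_circR_19347 was listed in every library and averaged 51763 ± 26118 SRPBM at sham, 62974 ± 38341 at 1 h, 88095 ± 10054 at 6 h, 95567 ± 24534 at 12 h and 78536 ± 3606 at 3 d (SD, n = 3 each).

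**Figure D2:**
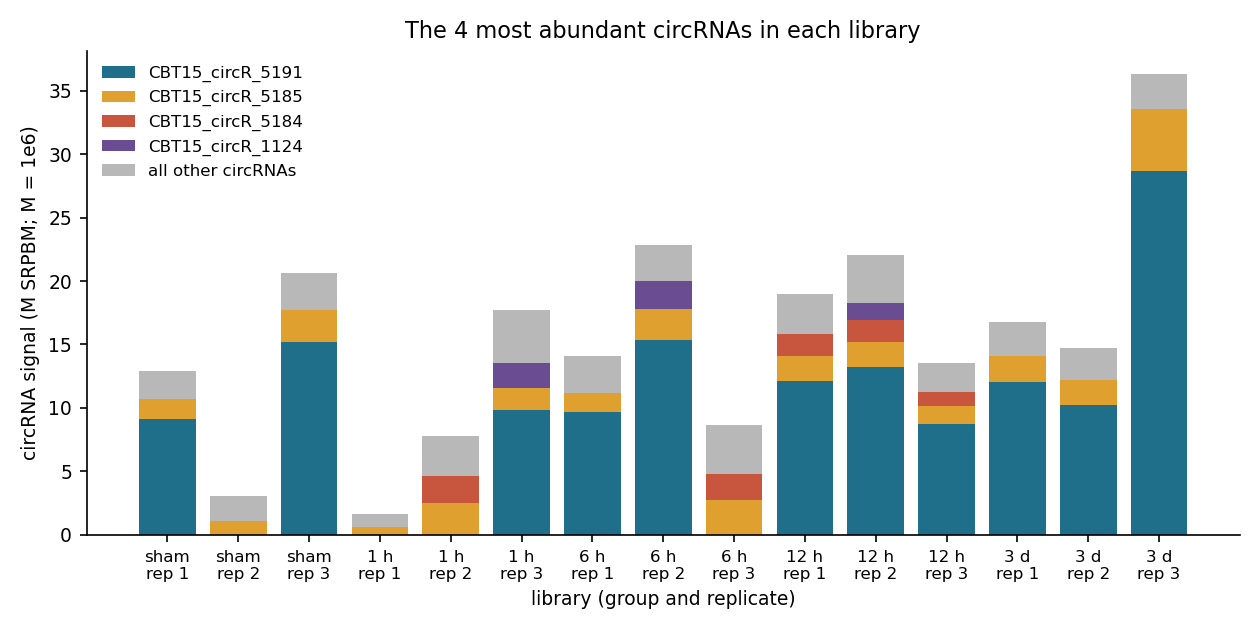
Stacked bars of circRNA signal (M SRPBM, axis from 0) in each of the 15 libraries, split into the 4 most abundant circRNAs and all others. CBT15_circR_5191 takes 55.6% or more of the signal where it is listed and is missing from 4 bars, in the sham, 1 h and 6 h groups.

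The first comparison asked which circRNAs differed from sham 1 h after modelling, within library set A&B. CBT15_circR_40191 rose: it was listed at 0, 0 and 615 SRPBM in the sham libraries and at 805, 2088 and 3119 at 1 h (log2 change 4.66, SE 0.86, limma adjusted p = 0.00196). Groups that do not overlap were a condition for naming it, so that gap adds no support. Without ties, 3 libraries against 3 do not overlap in 10% of cases by chance. CBT15_circR_2054 fell: it lay at 621, 878 and 371 SRPBM in sham and was listed at 0 in all 3 libraries at 1 h (limma adjusted p = 0.0143). The other 2 called circRNAs were CBT15_circR_5191, lower by limma with 2 of 3 libraries at 0 against 1 of 3 in sham (adjusted p = 0.00334), and CBT15_circR_5184, called higher on 1 h replicate 2 alone (adjusted p = 0.0242). The call of CBT15_circR_2054 held in 9 of 17 alternatives and was lost without any one sham library (adjusted p = 0.0796, 0.143 and 0.0852) or without 1 h replicate 2 or 3 (0.0515 and 0.106). CBT15_circR_5191 kept its call in 10 of 18 alternatives and CBT15_circR_5184 in 8 of 17. In all, limma called 4 of 16767 circRNAs, 2 higher and 2 lower, and 571 had an unadjusted p under 0.05, where 838 would come from chance. That count, also used below, assumes uniform p-values, which data with many zeros may not give, so it is a rough reference only. Without sham replicate 2 and 1 h replicate 1 it called 37, of which 33 were higher, and with each library scaled to its total circRNA signal 14 (11 higher, 3 lower). With the spread not tied to abundance, limma called 0, with 548 at an unadjusted p under 0.05, and CBT15_circR_40191 had adjusted p = 0.517. Unadjusted limma p then went from 5.76e-06 to 0.13 for CBT15_circR_5184 and from 3.99e-07 to 0.202 for CBT15_circR_5191. Voom called 6, with 2 of the 4 among them.

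At 6 h, CBT15_circR_36565 rose: it was listed at 0 in all 3 sham libraries and lay at 701, 869 and 1413 SRPBM at 6 h (limma adjusted p = 0.00224). CBT15_circR_5196 also rose, from 0, 0 and 939.5 SRPBM in sham to 2275, 2317 and 2364 at 6 h (log2 change 4.87, SE 1.03, adjusted p = 0.0126). The call of CBT15_circR_36565 held in 15 of 18 alternatives. That of CBT15_circR_5196 held in 9 of 17 and was lost without sham replicate 1 or 2 (adjusted p = 0.225 and 0.360) and without 6 h replicate 2 or 3 (0.0584 and 0.0573). In all, limma called 8 circRNAs, 8 of them higher and 0 lower, and 1299 had an unadjusted p under 0.05 against 838 from chance. No circRNA passed in the lower direction; the one with the smallest p there, CBT15_circR_11448, lay at 496, 1393 and 139 SRPBM in sham and at 0, 0 and 158 at 6 h (adjusted p = 0.621, and it passed in 1 of 18 alternatives). The median log2 change over all tested circRNAs was 0.46, and depended on the handling of low values: 1.56 with a pseudocount of 1 SRPBM, 0.092 with 10 times the main one, 0.83 with the filter of at least 8 libraries and 0 with no filter. It was 0.29 without sham replicate 2, 0.68 without sham replicate 3 and 0.38 with median-ratio scaling. The 6 h libraries were all in set C and the sham libraries all in set A&B, so time and library set cannot be told apart here. Without the libraries sham replicate 2 and 1 h replicate 1 limma called 24 circRNAs (22 higher). In that fit 864 of 16593 circRNAs had an unadjusted p under 0.05, fewer than the 1299 of the main fit. Since the chance level is uncertain, how much excess was left cannot be stated. With the spread not tied to abundance limma called 1.

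At 12 h, CBT15_circR_5184 lay at 1.69, 1.74 and 1.12 M SRPBM and was listed at 0 in all 3 sham libraries (limma adjusted p = 1.31e-28). CBT15_circR_36565 rose here too, from 0 in all 3 sham libraries to 693, 646 and 725 SRPBM (adjusted p = 0.00471). The call of CBT15_circR_5184 held in 15 of 17 alternatives. Over all groups this circRNA was all or none, at 1.12 to 2.11 M in 5 libraries and at 0 in the other 10. In those 10, CBT15_circR_5185 lay at 0.656 to 4.90 M. A failure in circRNA calling in single libraries was not tested for CBT15_circR_5184 and stays open. That of CBT15_circR_36565 held in 9 of 18 and was lost without any one 12 h replicate (adjusted p = 0.0647, 0.111 and 0.121). In all, limma called 8 circRNAs, 8 higher and 0 lower, with 1114 at an unadjusted p under 0.05 against 838 from chance, and called 1 without 12 h replicate 2 and 1 without replicate 3. Of the 8 at 6 h and the 8 at 12 h, 5 were shared; these comparisons use the same sham libraries. CBT15_circR_39077, the circRNA with the smallest p in the lower direction, lay at 699.5, 1181 and 81.2 SRPBM in sham and was listed at 0 in all 3 libraries at 12 h (adjusted p = 0.0576). It passed in 7 of 17 alternatives, among them no filter (adjusted p = 0.0263), scaling to total circRNA signal (0.0279) and voom (0.0143). The median log2 change was 0.43, and was 1.52 with a pseudocount of 1 SRPBM, 0.086 with 10 times the main one, 0.76 with the filter of at least 8 libraries and 0 with no filter. It was 0.22 without sham replicate 2 and 0.65 without sham replicate 3. Time and library set cannot be told apart, as at 6 h. Without the libraries sham replicate 2 and 1 h replicate 1 limma called 20 (20 higher). In that fit 732 of 16593 circRNAs had an unadjusted p under 0.05, fewer than the 1114 of the main fit. Whether an excess over chance was left cannot be stated, as at 6 h. Scaled to total circRNA signal limma called 6 (3 higher, 3 lower), and with the spread not tied to abundance CBT15_circR_5184 had adjusted p = 0.351.

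At 3 d, compared with sham within set A&B, CBT15_circR_40191 was higher at 1696, 1505 and 1255 SRPBM against 0, 0 and 615 (log2 change 4.42, SE 0.86, limma adjusted p = 0.00195). CBT15_circR_22046 rose from 0, 0 and 1449.9 SRPBM to 1696, 1505 and 2467 (log2 change 4.34, SE 0.91, adjusted p = 0.00769). CBT15_circR_2054 and CBT15_circR_11448 fell: both were listed in all 3 sham libraries and at 0 in all 3 libraries at 3 d (adjusted p = 0.00717 and 0.0274). Calls held in 8 of 18 alternatives for CBT15_circR_40191, in 9 of 17 for CBT15_circR_2054, and in 6 of 18 for CBT15_circR_22046 and for CBT15_circR_11448. Each of the last 3 was lost without sham replicate 1 or 2 and without any one 3 d replicate. CBT15_circR_40191 was lost too without sham replicate 2 and without 3 d replicate 3, where limma called 0. In all, limma called 9 circRNAs, 5 higher and 4 lower, and 756 had an unadjusted p under 0.05 against 838 from chance. The median log2 change was 0.20, and was 0.51 with the filter of at least 8 libraries, 0.45 without sham replicate 3, 0 without sham replicate 2 and 0 after scaling to total circRNA signal, with which limma called 7 (2 higher, 5 lower). Without sham replicate 2, or without 3 d replicate 3, limma called 0, and without 3 d replicate 1 it called 1. With the spread not tied to abundance it called 0, with 779 at an unadjusted p under 0.05, and voom called 5, with 3 of the 9 among them.

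CBT15_circR_40191 was called in each of the 4 comparisons with sham, with log2 changes of 4.66 at 1 h, 4.26 at 6 h, 4.22 at 12 h and 4.42 at 3 d (SE 0.86 each, limma adjusted p = 0.00196, 0.00731, 0.00471 and 0.00195). It lay between 769.7 and 3119 SRPBM in all 12 DVT libraries, above the highest sham library at 615. Groups that do not overlap were a condition for naming it, so this gap adds no support to its calls. Its call held in 11 of 18 alternatives at 1 h (adjusted p = 0.0829 without sham replicate 1 and 0.0553 without 1 h replicate 3) and in 8 of 18 at 3 d. A limma fit of only the 2 groups gave it adjusted p = 0.9997 at 1 h. At 3 d the call was lost without sham replicate 2 and without 3 d replicate 3. In a comparison added after the data were seen, the mean of the 4 times against sham, limma called 6 circRNAs (5 higher, 1 lower). In it CBT15_circR_40191 was at log2 change 4.39 (SE 0.68, adjusted p = 3.15e-06) and CBT15_circR_2054 was lower (adjusted p = 0.00295), and their calls held in 25 of 27 and 23 of 26 alternatives. Scaled to total circRNA signal limma called 7 (5 higher, 2 lower) and with median-ratio scaling 2 (1 higher, 1 lower), and within set A&B, with 1 h and 3 d against sham, it called 3. The calls shared between the comparisons with sham include chance from the sham libraries they share. In all, 7 circRNAs were called in at least 2 of the 4 comparisons, where 99 random regroupings of the 15 libraries gave a median of 3, up to 43, and 7 or more in 9 of the 99. A single circRNA was called in all 4, and 29 of the 99 regroupings gave at least 1 such circRNA, with up to 18. Regroupings could put sham replicate 2 and 1 h replicate 1, with few circRNAs each, in the same group, unlike the real grouping. How many did was not counted, so these numbers are a rough guide to chance. With 3 sham libraries, these could not be split into parts of 2.

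**Figure D3:**
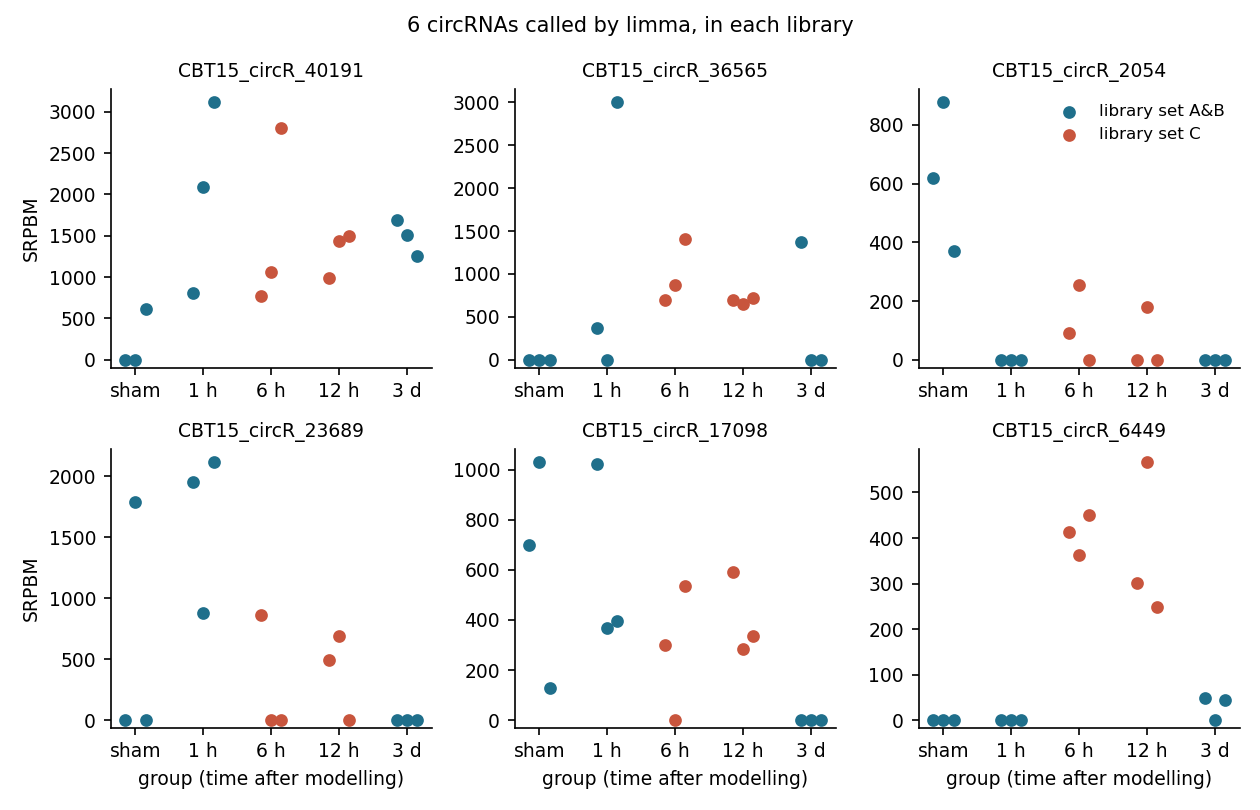
SRPBM (linear axes) of 6 circRNAs called by limma, with a point for each of the 15 libraries, by group and coloured by library set. CBT15_circR_40191 lies above 769 SRPBM in all 12 DVT libraries and at 615 or 0 in sham; CBT15_circR_23689 and CBT15_circR_17098 are listed at 0 in all 3 libraries at 3 d; CBT15_circR_6449 is above 248 in the 6 libraries of set C and below 48 in the 9 of set A&B.

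The comparison of 3 d with 1 h, both in set A&B, asked which circRNAs differed between the late and the early time. CBT15_circR_23689 lay at 1951, 878 and 2117 SRPBM at 1 h and was listed at 0 in all 3 libraries at 3 d (limma adjusted p = 5.07e-05). CBT15_circR_17098 likewise fell from 1023, 368 and 394 SRPBM to 0 in all 3 (adjusted p = 0.0141). In the other direction, CBT15_circR_40460 rose from 0 in all 3 libraries to 95.5, 959 and 1212 SRPBM (adjusted p = 0.018), and CBT15_circR_5191 was at 0, 0 and 9.85 M at 1 h and at 12.0, 10.2 and 28.7 M at 3 d (adjusted p = 2.08e-18). Calls held in 15 of 17 alternatives for CBT15_circR_23689, 13 of 18 for CBT15_circR_5191, and 8 of 18 for CBT15_circR_17098 and for CBT15_circR_40460. CBT15_circR_17098 lost its call without 1 h replicate 1 (adjusted p = 0.0706) and without any one 3 d replicate (0.110, 0.111 and 0.210). CBT15_circR_40460 lost it without 1 h replicate 3 (0.0542) and without 3 d replicate 2 or 3 (0.482 and 0.952). In all, limma called 6 circRNAs, 3 higher and 3 lower at 3 d, and 825 had an unadjusted p under 0.05 against 838 from chance. Scaled to total circRNA signal it called 23 (1 higher, 22 lower), and without the libraries sham replicate 2 and 1 h replicate 1 it called 65 (9 higher, 56 lower). With the spread not tied to abundance limma called 0, with 776 at an unadjusted p under 0.05, and voom called 7, with 3 of the 6 among them.

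The comparison of 12 h with 6 h, both in set C, gave 2 calls, both among the most abundant circRNAs. CBT15_circR_5184 was listed in all 3 libraries at 12 h and in 1 of 3 at 6 h (2.06 M SRPBM), with limma adjusted p = 1.37e-12. CBT15_circR_5191 lay at 12.1, 13.2 and 8.74 M at 12 h and at 9.66, 15.3 and 0 M at 6 h (adjusted p = 0.00713), and without 6 h replicate 3 its log2 change was -0.12. Calls held in 14 of 17 alternatives for CBT15_circR_5184 and 9 of 18 for CBT15_circR_5191. Scaled to total circRNA signal limma called 3 (2 higher, 1 lower). Unadjusted p was under 0.05 for 637 circRNAs against 838 from chance, and with the spread not tied to abundance limma called 0 (523 at an unadjusted p under 0.05). Voom called 2 other circRNAs, 1 higher and 1 lower, and shared 0 with the calls above.

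The mean of the 6 h and 12 h libraries was compared with the mean of the other 3 groups, to measure how far the 2 library sets lay apart. CBT15_circR_6449 was higher in set C, at 391 ± 113 SRPBM (SD, n = 6), and was listed at 0 in 7 of the 9 libraries of set A&B and at 47.8 and 43.3 in the others (log2 change 3.76, SE 0.63, limma adjusted p = 3.37e-05). CBT15_circR_4859 lay at 1048 ± 423 SRPBM in set C (n = 6) and between 0 and 450.4 in set A&B (log2 change 3.52, SE 0.63, adjusted p = 0.000165). CBT15_circR_20982 was lower in set C, at 0 in 5 of 6 libraries, and between 72.1 and 1045 SRPBM in all 9 libraries of set A&B (log2 change -2.93, SE 0.63, adjusted p = 0.0133). Calls held in 25, 24 and 17 of 26 alternatives for these 3, in this order. In all, limma called 13 circRNAs, 12 higher and 1 lower in set C, and 1604 had an unadjusted p under 0.05 against 838 from chance. Every group of set C is a different time from every group of set A&B, so library set and time cannot be told apart. Scaled to total circRNA signal limma called 9 (7 higher, 2 lower), and with the spread not tied to abundance 1.

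Nearly all calls rested on libraries listed at 0. A compared library was at 0 in 4 of the 4 circRNAs called at 1 h, 8 of 8 at 6 h, 8 of 8 at 12 h, 7 of 9 at 3 d, 5 of 6 between 3 d and 1 h and 2 of 2 between 12 h and 6 h. The 2 calls at 3 d with no zero were CBT15_circR_5185 (log2 change 0.76, SE 0.14) and CBT15_circR_22135 (log2 change -2.64, SE 0.46), named here after their values were seen. The SRPBM values of their groups overlapped. CBT15_circR_5185 lay at 1.54, 1.07 and 2.56 M SRPBM in sham and at 2.10, 1.99 and 4.90 M at 3 d. CBT15_circR_22135 lay at 85893, 92711 and 35842 SRPBM in sham and at 4837, 40887 and 5973 at 3 d. These SEs come from the spread tied to abundance, and without that tie limma called neither. In 20 simulated tables with no circRNA changed, the same test made a median of 7 calls for 1 h against sham (highest 18), 6.5 for 6 h (14), 6 for 12 h (20) and 6.5 for 3 d (18). It made a median of 6 calls for 12 h against 6 h (14), 8 for 3 d against 1 h (17), 0.5 for the library sets (11) and 5 for all DVT times (12). Only the count between library sets lay above its simulated range. The simulated tables drew zeros separately in each library and held no library with few circRNAs, so that range lacks this structure. Random regroupings of the real libraries gave up to 28 calls for the sets. Of 100 groupings, the real one included, 7 gave at least 13. Regroupings could put sham replicate 2 and 1 h replicate 1 in the same group, unlike the real grouping.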

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

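All tests of explanations in this part were chosen after the result was seen. The comparisons of 3 d with 1 h and of 12 h with 6 h, which are also tests of whether the changes from sham differ between times, drew attention because some circRNAs passed. Between 3 d and 1 h, 6 circRNAs differed, among them CBT15_circR_5191 (log2 difference 13.09). For 4 others a compared group was listed at 0 in all 3 libraries, so that only limma adjusted p is given. These were CBT15_circR_40460 (0.018), CBT15_circR_23689 (5.07e-05), CBT15_circR_17098 (0.0141) and CBT15_circR_5184 (0.018). The last, named here after its values were seen, was above 0 at 1 h in replicate 2 alone. Between 12 h and 6 h, 2 circRNAs differed, CBT15_circR_5184 (log2 difference 10.49) and CBT15_circR_5191 (6.21). The log2 differences depend on the pseudocount, since each involves libraries listed at 0.

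For groups of 3, the libraries make 10 splits, too few for a share under 0.05. The real value and the highest of the other splits were 4 and 1246 for 1 h against sham (6 splits with as many calls, the real split included), 8 and 6 for 6 h (1 split), 8 and 6 for 12 h (1 split), and 9 and 3 for 3 d (1 split). They were 2 and 3 for 12 h against 6 h (4 splits), and 6 and 8 for 3 d against 1 h (2 splits). The split with 1246 calls points to a structure of the samples: in the 4 splits of the sham and 1 h libraries that put sham replicate 2 and 1 h replicate 1 together, limma called from 17 to 1246 circRNAs, and from 0 to 4 in the 6 that parted them. For the library sets, 7 of 100 splits gave as many as the 13 calls (highest other 28). For all DVT times against sham 30 of 100 gave as many as the 6 (highest other 401), so chance cannot be excluded for either. The regroupings among these 100 could put sham replicate 2 and 1 h replicate 1 in the same group, which the real grouping does not.

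A first pattern is the low number of circRNAs in sham replicate 2 and 1 h replicate 1. Fewer mapped reads are argued against, because after thinning every library to 66.0 M mapped reads the larger of the ratios to the other libraries of the group was 0.30, and so is membership of the sham or 1 h group, since the other 4 libraries of these groups held at least 0.88 of the circRNAs of the median library. Random loss of molecules and a shared shift in which circRNAs the libraries hold both stay open. Over the 805 circRNAs with a mean of at least 50 reads, the deviations of the 2 libraries from their groups were related (rho = 0.48 across circRNAs, against -0.28 to 0.28 in 27 pairs of libraries from the other 3 groups). Differences within a group between libraries outside this pair had a median rho of 0.13 in size over 46 pairs and reached 0.54 in 1 of them, so a relation of this strength also occurs outside the 2 libraries, and these explanations cannot be told apart.

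A second pattern is that CBT15_circR_5191, elsewhere the most abundant circRNA, was listed at 0 in 4 libraries. Where listed it kept a ratio of 5.15 to 6.66 to CBT15_circR_5185, so at least 247657 back-spliced reads would be expected in each of the 4 libraries, which argues against counting noise. Reads listed under a neighbouring number are argued against, since the 10 numbers on each side summed to at most 0.83 of CBT15_circR_5185. Time after modelling is argued against as the whole cause, since no group had more than 2 of its libraries at 0. A failure in circRNA calling in single libraries was not tested and stays open, and calls on this circRNA (all comparisons that name it) rest on which libraries are at 0. The same limit holds for CBT15_circR_5184, listed at 1.12 M SRPBM or more in 5 libraries and at 0 in 10.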

How the results depend on the processing

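Array weights, voom, zeros as missing, the fits without sham replicate 2 and 1 h replicate 1, and the fit of all DVT times, also within set A&B only, were chosen after seeing the data. Counts of calls were 4 for 1 h, 8 for 6 h, 8 for 12 h and 9 for 3 d against sham, 2 for 12 h against 6 h, 6 for 3 d against 1 h, 13 for the library sets and 6 for all DVT times. In this order they became 0, 0, 1, 0, 0, 0, 0 and 1 with a pseudocount of 1 SRPBM; 0, 0, 0, 0, 0, 0, 2 and 1 above 0 in at least 8 libraries. They became 0, 1, 1, 0, 0, 0, 1 and 1 without the trend; 0, 0, 0, 0, 0, 0, 3 and 0 with zeros as missing. They became 703, 160, 168, 137, 3, 102, 61 and 821 with array weights, and 37, 24, 20, 7, 5, 65, 32 and 26 without the 2 libraries. With array weights, other splits of the same libraries reached 2867 calls for 1 h (6 of 10 splits gave at least the 703) and 75 for 3 d against 1 h, and without the 2 libraries 13 for 1 h. At an unadjusted p under 0.05 the fits with no call against sham at 1 h held 437, 215, 548 and 264 circRNAs (pseudocount 1, 8 libraries, no trend, zeros as missing), and voom called 6. With 10 times the pseudocount the counts were 2 for 1 h, 1 for 3 d and 1 for all DVT times. With no filter they were 10 for 1 h, 13 for 12 h, 6 for 12 h against 6 h, 13 for 3 d against 1 h, 20 for the sets and 11 for all DVT times. Scaled to total signal they were 14 for 1 h, 5 for 6 h and 23 for 3 d against 1 h, and with median-ratio scaling 2, 3 and 3 for 1 h, 6 h and 12 h, 1 for 12 h against 6 h and 2 for all DVT times. Fits of only the 2 groups gave 15 for 6 h, 13 for 12 h and 15 for 12 h against 6 h. For 1 h such a fit gave 3 (0 higher, 3 lower), of which 1 was among the 4 of the main fit. There CBT15_circR_40191 and CBT15_circR_2054 each had limma adjusted p = 0.9997. Voom gave 5 for 6 h, 5 for 3 d and 13 for all DVT times, and set A&B alone 3 for all DVT times. The cause of these moves was not tested, except that fewer circRNAs are tested with the stricter filter. Low circRNAs were often listed at 0, and whether depth was the cause was not tested. A median of 4 to 8 reads went with 29.9% of values at 0 among circRNAs above 0 in at least 7 of 13 libraries. For the same circRNAs the share was 92.3% in sham replicate 2 and 1 h replicate 1.

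Leaving out a replicate in turn gave 1 to 19 calls for 1 h (1 without sham replicate 3, 19 and 7 without 1 h replicates 1 and 2). The range was 3 to 12 for 6 h (3 without sham replicate 2, 4 and 3 without 6 h replicates 2 and 3). It was 1 to 19 for 12 h (4 and 19 without sham replicates 2 and 3, 5, 1 and 1 without 12 h replicates 1, 2 and 3). It was 0 to 14 for 3 d (4, 0 and 14 without sham replicates 1, 2 and 3, 1 and 0 without 3 d replicates 1 and 3). It was 1 to 2 for 12 h against 6 h (1 without 12 h replicate 2 or 3) and 2 to 22 for 3 d against 1 h (22 and 16 without 1 h replicates 2 and 3, 2 without 3 d replicate 3). It was 5 to 22 for the sets (5 without 12 h replicate 2, 22 without 1 h replicate 3) and 3 to 118 for all DVT times (118 without 1 h replicate 1, 27 without sham replicate 3). CBT15_circR_5191 between 12 h and 6 h ran from -0.12 (without 6 h replicate 3, the library where it is listed at 0, against 6.21) to 9.55 when a replicate was left out. The log2 ratio of total SRPBM between 3 d and 1 h, 1.32, was -0.058 without the 10 most abundant circRNAs and -0.15 as a median over circRNAs in every library. Of the named circRNAs' other alternatives, 446 kept their direction and side of the threshold, 156 lost the call without turning direction (1 of them, CBT15_circR_5184 at 1 h without 1 h replicate 2, at a log2 change of 0) and 30 gained it.

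The replicate numbers share only a number. For same-numbered libraries, correlations of their deviations from the group means ran from -0.18 to 0.12. By these deviations 5 of 15 libraries correlated best, outside their own group, with a library of their own number. That count was not set against chance. With the replicate number as a block the counts were 6, 9, 13, 10, 3, 11, 15 and 9 in the order above, and 3 named circRNAs passed that did not in the main fit, CBT15_circR_39077 and CBT15_circR_20982 at 12 h and CBT15_circR_22135 for all DVT times (adjusted p = 0.0259, 0.0434 and 0.0135). Not run were edgeR and DESeq2 on recovered reads, since the table holds no value of 1 read and so lacks the lowest counts, and the host gene results, host gene lists and title circRNA, since identifiers are not paired with genes.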

Other observations

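All values in this part were chosen after the data were seen. CBT15_circR_22135, the circRNA with the seventh highest mean, was listed in all 15 libraries at 2 separate levels: 3983 to 5973 SRPBM in 4 libraries (1 h replicate 1, 12 h replicate 3, 3 d replicates 1 and 3) and 35842 to 103409 SRPBM in the other 11, a 6.00-fold gap. Its group means were 71482 ± 31053 SRPBM at sham, 58249 ± 50335 at 1 h, 52638 ± 17688 at 6 h, 34252 ± 26833 at 12 h and 17232 ± 20494 at 3 d (SD, n = 3 each).

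CircRNAs listed in all 3 libraries of a group and in none of the other 12 numbered 0 for sham, 3 at 1 h, 23 at 6 h, 11 at 12 h and 1 at 3 d. The counts for sham and 1 h are limited by sham replicate 2 and 1 h replicate 1, which hold few circRNAs. Those listed in all 3 libraries, whatever the other groups, numbered 1776 for sham, 1748 at 1 h, 5708 at 6 h, 5668 at 12 h and 4483 at 3 d. Among the 455 ways to choose 3 of the 15 libraries, the median was 5 and the highest 54, and 25 gave as many as the 6 h group. The 455 include sets with sham replicate 2 or 1 h replicate 1, which the 6 h group does not hold, so 23 may be more common among like libraries.

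Among the 805 abundant circRNAs, 159 lay at least 4-fold below the rest of their group in both sham replicate 2 and 1 h replicate 1, which is 19.8% against 13.9% for independent libraries. A further 85 (10.6%, against 6.20% for independent libraries) lay no lower than -0.50 on the log2 scale in both. The deviation of 1 h replicate 1 also followed the difference between sham replicates 1 and 3 (rho = 0.46 across circRNAs, which are not independent replicates).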
